A study of Mus musculus with 8 samples.

How the data were processed

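Gene expression was measured with Affymetrix microarrays in retinas of mouse pups at postnatal day 8 (P8). Z/Edn2 is a Cre-dependent transgene that carries Edn2, and Six3-Cre drives recombination in the developing retina. The 4 Z/Edn2 samples came from pups that inherited the Z/Edn2 allele, recognised by LacZ activity in tail clips, and the 4 Control samples from Six3-Cre pups without it. Per the labels, the mice were of mixed background, each sample pooled the retinas of 2 to 3 pups, and the arrays were called biological replicates. The p-values therefore measure the spread between these 8 pools. Total RNA was labelled with biotin by the Affymetrix 3′ IVT Express kit.

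The deposited value table holds log2 signal per probe set, which the authors made with RMA (background correction, quantile normalization and summary of the probes of each probe set); the version was not given. The values were used as deposited, without a further log or scaling step. The authors' deposited comparison holds, for each probe set, a log2 fold change, a signed fold change (a score that is negative for lower expression) and an unadjusted p-value from a test that was not named. The authors' log2 fold changes equalled the differences of the group means of the value table, Z/Edn2 minus Control, within 4.9e-08, which fixed the direction of the comparison. All log2 fold changes here are Z/Edn2 minus Control.

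Of 45101 probe sets, 64 were controls of the array, 34945 had 1 gene symbol, 932 had several symbols and 9160 had none. Only probe sets with 1 symbol entered the gene comparison, and each gene was represented by its probe set with the highest mean over the 8 arrays, which left 18193 genes, 9010 of them with more than 1 probe set. Of the named probe sets, 34741 were found by Entrez identifier in a RefSeq gene table of the assembly GRCm38.p6, and 0 symbols changed. That table was used for gene names and gene order only, since no genome build was named for the arrays. The number of arrays limits the precision. Pearson correlations between arrays lay between 0.982 and 0.996.

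Genes were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. No filter on dim probe sets was applied. Fold changes are given with limma's standard error (SE). Comparisons of a single value or of a list mean used a two-sided exact permutation test of 4 against 4 arrays, whose smallest possible p is 0.0286. Of these exact tests only that of Edn2 was planned, and those of list means and of differences between lists were not. The groups, the limma tests of genes and gene lists, the first set of alternatives, the gene lists and the rule for named genes were chosen before the data were examined. The rule took Edn2, then up to 12 genes per direction with the largest changes among those past the threshold whose 4 Z/Edn2 values all lay on one side of the 4 Control values, then up to 4 members with the smallest p-values of each list described by examples.

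The gene lists numbered 31 and were written from general knowledge, with 440 entries of 437 different genes, of which 33 entries had no usable probe set. They covered endothelial tip cells, general endothelium, barrier endothelium, the Norrin-Frizzled4 pathway, mural cells, basement membrane, hypoxia response, glycolysis, angiogenic and vascular guidance factors, and the endothelin pathway. Further lists covered reactive glia, Mueller glia, astrocytes, rods, cones, bipolar, amacrine, horizontal and retinal ganglion cells, proliferation and retinal progenitors. The remaining lists were microglia and macrophages, erythroid cells, retinal pigment epithelium, lens, fibroblasts, immediate early genes, unfolded protein and amino acid stress, interferon response, cholesterol synthesis and sex-linked genes. Lists with at least 3 measured genes were tested with camera, limma's competitive test, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Each list was also tested with a correlation estimated from the data, with ranks, and with fry, limma's self-contained test. Members were also adjusted over the list alone. The part of a list's mean change that a covariate accounted for was taken as its slope within groups times its difference between groups, with a 95% bound from the errors of both.

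Replicate numbers were shared between the groups, but the labels did not say what a number shared. After removal of the group means, arrays with the same number had correlations across genes of 0.72, 0.39, 0.15 and 0.28, each above the bound of 0.1, so a fit with the replicate number as a block was run beside the unblocked one. Control 3 also correlated at 0.22 with Z/Edn2 4 and at 0.16 with Z/Edn2 2, both above the 0.15 of replicate 3. The bound thus did not single out same-numbered arrays, and the pairing of replicate 3 had little support. This first set of alternatives held eBayes with trend and robust options, removal of probe sets below the median signal, the mean of a gene's probe sets, another round of quantile normalization, median centring, array weights (statmod 1.5.0), the replicate block, counting every probe set, a fold threshold of 1.5, other Edn2 probe sets, the other list tests, and the omission of each array in turn. Chosen after seeing the data were the mean of Y-linked genes as a covariate, the omission of 3 arrays that stood apart, the omission of each same-numbered pair, and the block together with an estimated correlation. That last setting leaves few residual degrees of freedom with so few arrays, so its power was low and a lost call there decides little. On simulated data with 18193 genes, the comparison recovered 64% of 100 genes changed 1.5-fold and 94% of 100 genes changed 2-fold, and 11 of its 177 calls were false (6.21%). The genes of the general endothelial list were also shifted there and counted as true. The simulated noise was independent between genes and arrays, without pair effects, correlated genes or an outlying array. These rates therefore need not hold for the measured data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.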

Results

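The data comprised 8 arrays of P8 retina, 4 from Z/Edn2; Six3-Cre pups and 4 from Six3-Cre Control pups, with a log2 signal for each of 18193 genes. Array medians lay between 6.14 and 6.28. Z/Edn2 3 stood apart from the other arrays. Its median was 6.28, its bioD spike-in signal at the 5′ end was 9.30 against 11.3 to 11.6 elsewhere, and Xist, the RNA of the inactive X chromosome, was at 6.57 against 10.2 to 12.4. Its mean for the Y-linked genes Eif2s3y, Uty and Kdm5d was 8.19 against 6.40 to 7.53. Control 1 and Z/Edn2 1 differed from the others in the actin signal at the 3′ end minus that at the 5′ end. This log2 difference was 0.65 and 0.56 in these arrays against 1.06 to 1.42 elsewhere.

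The comparison of Z/Edn2 with Control asked how the retina and its vessels differed when Six3-Cre pups also carried the Edn2 transgene. Edn2, the gene of the secreted vasoconstrictor peptide endothelin 2, had a single probe set, at 3.98 ± 0.125 in Control and 4.16 ± 0.129 in Z/Edn2 (log2 signal, mean ± SD, n = 4 each). Its log2 fold change was 0.18 ± 0.0951 (SE), which did not pass (limma adjusted p = 0.971, or 0.485 with the replicate block, and exact permutation p = 0.143). Within each same-numbered pair the Z/Edn2 value was the higher. The sources used here did not say whether this probe set lies within the transgene's transcript, so it gave no check of the genotype labels. Of the 6 measured genes of the endothelin pathway list, 0 passed by limma, 0 passed when adjusted over the list alone, and 0 had an unadjusted p under 0.05. Ece2, an endothelin-converting enzyme, had a log2 fold change of 0.14, Ednrb, the endothelin B receptor, 0.11, and Ece1, another converting enzyme, 0.06. The list's camera adjusted p was 0.276. The direction of Ece1 turned without Control 2 (−0.11), without Z/Edn2 1 and without Z/Edn2 4, and that of Ednrb without the pair of replicate 1 (−0.010).

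Genes of the hypoxia response rose in Z/Edn2 retina, while several genes of the general and barrier endothelial lists fell. Dlk1, a Notch-related membrane protein of immature cells, was 5.45-fold higher, Ndufa4l2, a mitochondrial protein induced by hypoxia-inducible factors, 5.06-fold, and Adm, the vasodilator peptide adrenomedullin, 4.78-fold. Slco1c1, a thyroid hormone transporter of brain and retinal vessels, fell by 2.50 on the log2 scale, and Aplnr, the apelin receptor, fell by 2.05. Of 18193 genes, 31 were higher and 9 lower by limma, 40 in all, and all 40 had no overlap between the 4 Z/Edn2 and 4 Control values. Among all genes 670 (3.68%) had no overlap, where chance gives 2.86%. An unadjusted p under 0.05 was reached by 958 genes, 655 higher and 303 lower, with 909.65 expected by chance. With the replicate block, 71 genes were higher and 26 lower, 97 in all, including all 40. The count of higher genes was 16 without Control 1, 16 without Control 3, 15 without Control 4, 20 without Z/Edn2 3 and 16 without Z/Edn2 4. Both counts also fell when same-numbered pairs were left out, to 11 higher and 3 lower without replicate 2, 12 and 3 without replicate 3, and 8 and 1 without replicate 4.

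**Figure D1:**
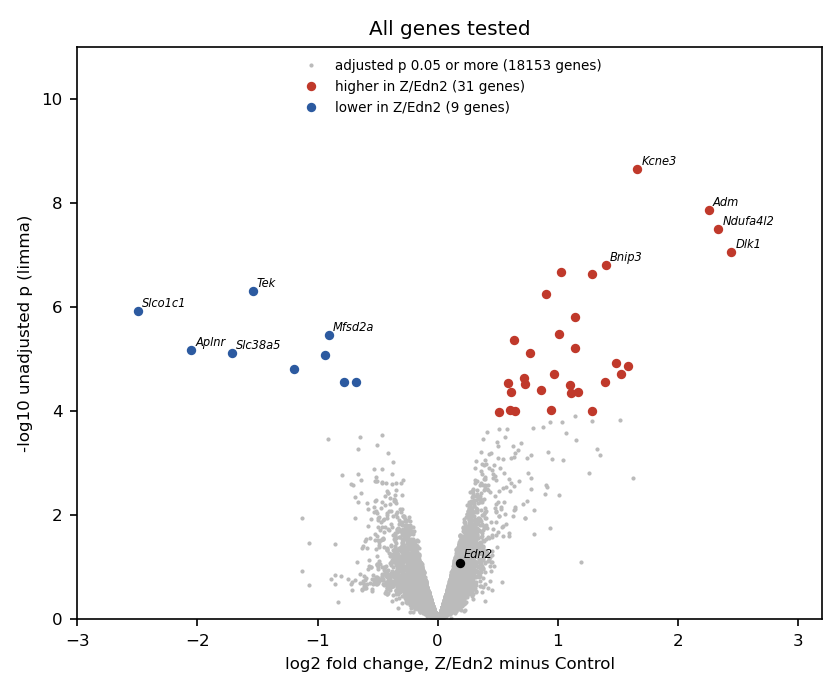
Each point is a gene, with its log2 fold change (Z/Edn2 minus Control) on the horizontal axis and minus log10 of the unadjusted limma p on the vertical axis. The 31 genes called higher and 9 called lower are coloured, and Edn2, in black, lies among the uncalled genes.

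Among the 12 named genes with the largest rises, Dlk1 went from 6.18 ± 0.243 in Control to 8.63 ± 0.365 in Z/Edn2 (log2 signal, SD, n = 4 each; limma adjusted p = 0.000394), although its other probe set had a log2 fold change of 0.061 and the mean of its probe sets 1.25. Ndufa4l2 rose by 2.34 ± 0.156 (SE; adjusted p = 0.000191) and Adm by 2.26 ± 0.138 (adjusted p = 0.000123). Kcne3, an accessory subunit of potassium channels, rose by 1.66 ± 0.0844 and had the smallest adjusted p, 4.03e-05, from a Control level that only 2.86% of genes lay below. Bnip3, a mitochondrial protein of mitophagy, rose by 1.40 ± 0.110, and Muc2, a secreted mucin, by 1.29 ± 0.106, both in 4 of 4 arrays above every Control array. Igfbp2, which binds insulin-like growth factors, rose by 1.49 (adjusted p = 0.0111), and Dlx1, a homeobox factor of inhibitory neurons, by 1.58 (adjusted p = 0.0118). Egln3, an oxygen-sensing prolyl hydroxylase, rose by 1.53 (adjusted p = 0.0148) and Esm1, a proteoglycan secreted by endothelial tip cells, by 1.39 (adjusted p = 0.0183). Tesc, a calcium-binding protein, rose by 1.17 (adjusted p = 0.0235), and A2m, a secreted protease inhibitor, by 1.28 (adjusted p = 0.0473). Of the 8 omissions of a single array, Dlx1 and Igfbp2 lost their calls in 3, Egln3 in 5, Esm1 and Tesc in 6 and A2m in 7. The highest adjusted p was 0.0636 for Dlx1, 0.121 for Tesc and 0.206 for A2m, each without Z/Edn2 4, 0.0747 for Egln3 and for Esm1 without Control 3, and 0.0586 for Igfbp2 without Control 4.

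The 9 lower genes included Tek and Ptprb of the general endothelial list and Slco1c1, Slc38a5 and Mfsd2a of the barrier list. Slco1c1 went from 6.74 ± 0.552 in Control to 4.24 ± 0.259 in Z/Edn2, and Aplnr from 8.70 ± 0.349 to 6.64 ± 0.495 (log2 signal, SD, n = 4 each; limma adjusted p = 0.00215 and 0.00768). Slc38a5, a glutamine transporter, fell by 1.71 ± 0.205 (adjusted p = 0.00768), and Tek, the angiopoietin receptor, fell by 1.54 ± 0.137 (adjusted p = 0.00113). Slc39a8, a zinc and manganese transporter, fell by 1.20, Pltp, a phospholipid transfer protein, fell by 0.94, and Mfsd2a, the lipid transporter of barrier endothelium, fell by 0.91. Ptprb, an endothelial receptor phosphatase, fell by 0.78, and AU021092, of which no function is stated here, fell by 0.68 (adjusted p = 0.0183 for each). As the mean of a gene's probe sets, the log2 fold change was −1.22 for Aplnr, whose other probe set was at −0.39, −0.77 for Slc39a8, and −0.54 for Ptprb, which then lost its call (adjusted p = 0.283). Slc39a8 lost its call without Control 3 (adjusted p = 0.0639), Ptprb in 5 of the 8 omissions of an array and AU021092 in 6, with the highest adjusted p, 0.0916 for each, without Control 4. Without the pair of replicate 4 the calls of Aplnr (adjusted p = 0.196), Slco1c1 (0.0715), Tek (0.059), Mfsd2a (0.125) and Pltp (0.125) were lost too, and that of Slc38a5 without replicate 3 (0.157).

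**Figure D2:**
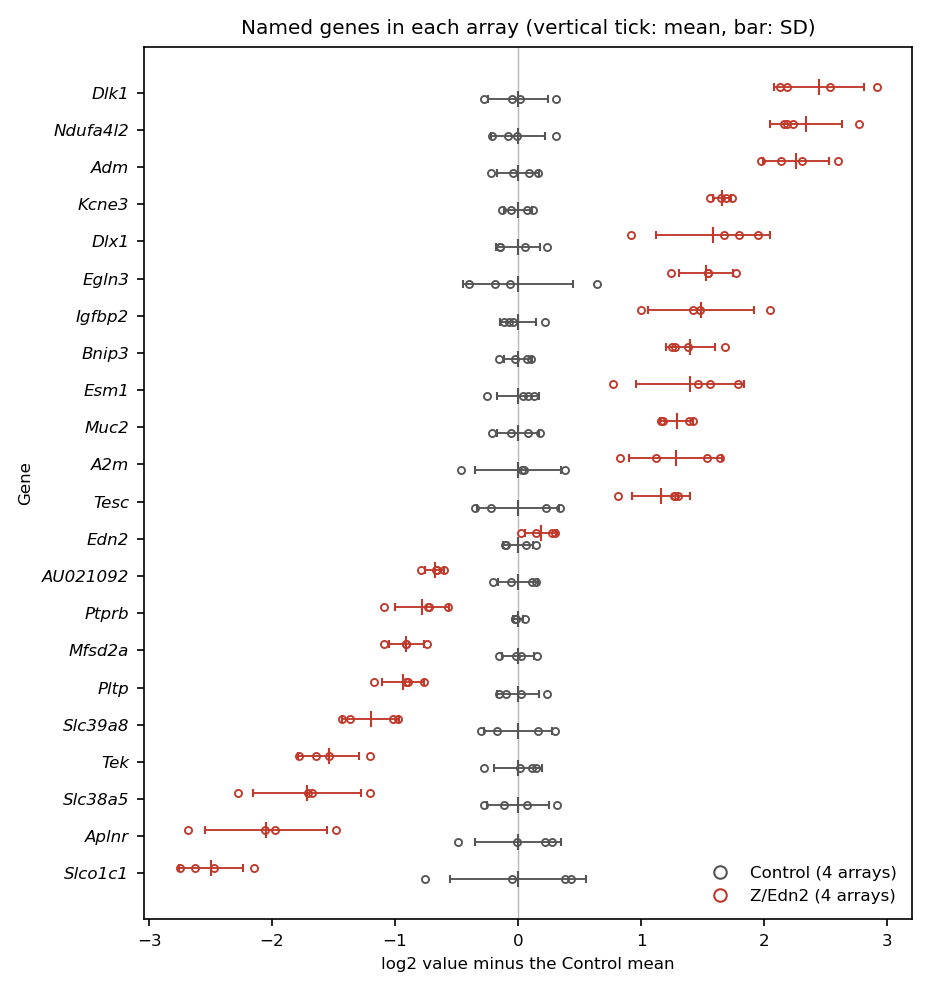
Each point is the log2 signal of a named gene on a single array, relative to the Control mean of that gene, with bars for the group mean and SD (n = 4 each). Every called gene shown separates the 4 Z/Edn2 arrays from the 4 Control arrays, while the values of Edn2 overlap.

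The hypoxia response list moved further than any other of the 31 lists. Of its 28 measured members, 7 rose over all genes tested, 0 fell, and 23 rose when adjusted over the list alone. Besides Adm and Bnip3, Pfkfb3, an activator of glycolysis, rose by 1.14 ± 0.115 (limma adjusted p = 0.00262), and Pdk1, which restrains pyruvate use by mitochondria, by 1.14 ± 0.134 (adjusted p = 0.00748). The mean log2 change of the list was 0.69, with Z/Edn2 arrays at 0.66 to 0.78 and Control arrays at −0.080 to 0.081 around the Control mean. Its camera adjusted p was 3.28e-39, or 0.0046 with an estimated correlation, and the exact permutation p was 0.0286. With the replicate block as well as an estimated correlation the adjusted p was 0.175, which ended the call in a setting of low power. The count of 7 became 14 with the replicate block, 11 with array weights, 4 without Control 3 or Control 4, and 2, 4 and 3 without the pairs of replicate 2, 3 and 4. Pfkfb3 lost its call without replicate 2 (adjusted p = 0.0535) and Pdk1 without replicate 4 (0.196).

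Genes of glycolysis rose as a list, with a mean log2 change of 0.33 (camera adjusted p = 6.76e-07), but the call was lost with an estimated correlation (adjusted p = 0.211) and by fry (adjusted p = 0.094). Of 10 measured members, 1 rose over all genes and 5 when adjusted over the list alone. Tpi1, triosephosphate isomerase, rose by 0.60 ± 0.0966 (limma adjusted p = 0.0465). Pfkp, a phosphofructokinase, had a log2 fold change of 0.80 (adjusted p = 0.0828, or 0.0222 with the replicate block), Pgam1, a phosphoglycerate mutase, 0.42 (adjusted p = 0.357), and Pfkl, another phosphofructokinase, 0.64 (adjusted p = 0.61). The call of Tpi1 was lost in each of the 8 omissions of an array, up to an adjusted p of 0.200 without Control 3.

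Endothelial genes did not move as a block. Tip cell genes, which mark the leading cells of growing sprouts, rose as a list by a mean of 0.36 on the log2 scale, while the general endothelial list fell by 0.27 and the barrier list, with the transporters of the blood-retina barrier, fell by 0.45. With an estimated correlation the tip cell and general calls were lost (adjusted p = 0.211 and 0.204) and the barrier call was kept (adjusted p = 0.0206), but with the replicate block as well it was lost too (adjusted p = 0.175). By fry the tip cell and general calls were also lost (adjusted p = 0.0881 and 0.101). Of 15 tip cell genes, 2 rose over all genes and 7 when adjusted over the list alone. Positive log2 fold changes numbered 13 and negative ones 2. The latter were Kdr and Flt4, at −0.23 each, named after their values were seen. Besides Esm1, Apln, the peptide apelin, rose by 0.63 ± 0.0715 (limma adjusted p = 0.0057, or 0.125 without replicate 4). Igfbp3, a binder of insulin-like growth factors, had a log2 fold change of 1.35 (adjusted p = 0.176, or 0.0361 with the replicate block) and Cxcr4, a chemokine receptor, 0.48 (adjusted p = 0.338). The tip cell list passed camera with the preset correlation (adjusted p = 9.67e-07), but its mean in Z/Edn2 2 was −0.019 around the Control mean, and the exact permutation p was 0.114, with 3 of 4 pairs higher. Of 20 general endothelial genes, 2 fell over all genes (Tek and Ptprb) and 7 when adjusted over the list alone. The list was mixed, with 15 negative and 5 positive log2 fold changes and a median of −0.16. Pecam1 was at 0.063, Flt1 at 0.062 and Cdh5 at −0.23 ± 0.294 (SE), all named after their values were seen. Cldn5, a tight junction protein, had a log2 fold change of −0.91 (adjusted p = 0.113), and Ramp2, an adrenomedullin receptor subunit, −0.41 (adjusted p = 0.168). This list's camera adjusted p was 1.22e-09 with the preset correlation, and the exact permutation p was 0.0286. Without Control 1, Z/Edn2 1 and Z/Edn2 3 the mean log2 change was 0.20 for the tip cell list and −0.44 for the general list, and without replicate 2 that of the general list was −0.16.

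Of 15 barrier endothelial genes, 13 had negative and 2 positive log2 fold changes, with a median of −0.20. Over all genes 3 fell (Slco1c1, Slc38a5 and Mfsd2a). Adjusted over the list alone, 5 were lower and 1 higher. The higher gene was Slc2a1, the glucose transporter that the hypoxia list also holds, at 0.33, named after its values were seen. Abcb1a, a drug efflux pump, had a log2 fold change of −0.51 (limma adjusted p = 0.505). The list passed camera (adjusted p = 1.22e-09), with an exact permutation p of 0.0286, and lost its call when dim probe sets were left out (adjusted p = 0.224). That filter removed Slco1c1, Slc38a5 and Mfsd2a, which were then not tested. The count of 3 was 1 without replicate 3 or replicate 4. The tip cell mean minus the general endothelial mean was 0.63 higher in Z/Edn2 than in Control (SD 0.124 and 0.0754, n = 4 each; exact permutation p = 0.0286). The barrier mean minus the general mean differed by −0.18 (SD 0.157 in Z/Edn2, exact permutation p = 0.143), which did not pass. Neither difference was a planned test. The tip cell and general lists were compared after they were seen to move apart, so the exact permutation p of 0.0286 gives no independent support.

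**Figure D3:**
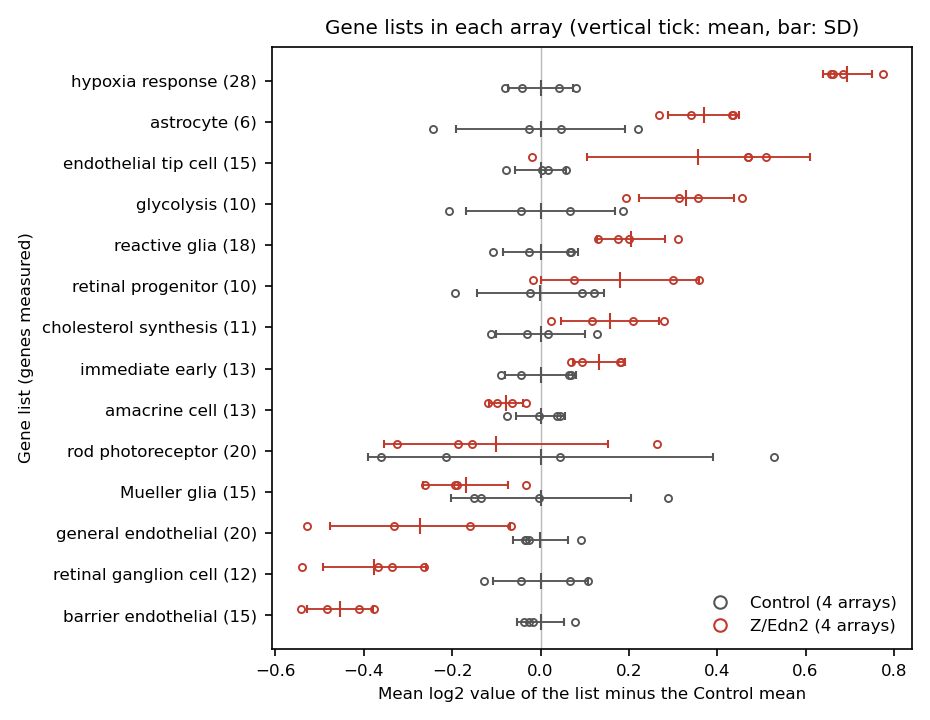
Each point is the mean log2 signal of a gene list on a single array, relative to the Control mean of that list, with bars for the group mean and SD (n = 4 each). The 4 Z/Edn2 arrays lie between 0.66 and 0.78 for hypoxia response, above all Control arrays, and below all Control arrays for the barrier endothelial, general endothelial and retinal ganglion cell lists.

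By camera 2 glial lists were higher and 1 lower, but each call was lost with an estimated correlation, and the lists were not tested against each other. The astrocyte list rose by a mean of 0.37 (camera adjusted p = 0.000227) and the reactive glia list by 0.20 (camera adjusted p = 0.000838), each with an adjusted p of 0.0844 with an estimated correlation and an exact permutation p of 0.0286. Of 6 astrocyte genes, 0 passed over all genes, 4 had an unadjusted p under 0.05 and 4 rose when adjusted over the list alone. They were Igfbp5, a binder of insulin-like growth factors, with a log2 fold change of 0.74 (limma adjusted p = 0.517, or 0.0112 with the replicate block), Slc14a1, a urea transporter, 0.68 (0.34, or 0.0318 with the block), Pdgfra, the receptor of retinal astrocyte precursors, 0.49 (0.536), and Aldh1l1, a folate enzyme of astrocytes, 0.46 (0.333). As the mean of their probe sets Igfbp5 was at 0.49 and Aldh1l1 at 0.26. Of 18 reactive glia genes only A2m rose, over all genes and over the list alone, while Vim, an intermediate filament protein, had a log2 fold change of 0.34, Steap4, a metal reductase, 0.25, and Gbp2, an interferon-induced GTPase, 0.21. The Mueller glia list fell by a mean of 0.17 (camera adjusted p = 0.0163, or 0.343 with an estimated correlation; exact permutation p = 0.143, with all 4 pairs lower), and 0 of its 15 genes passed over all genes, with 3 at an unadjusted p under 0.05 and 1, Sox9, higher when adjusted over the list alone. Sox9, a glial transcription factor, had a log2 fold change of 0.56 (adjusted p = 0.107, or 0.021 with the block), Abca8a, a lipid transporter, −1.13 (0.695, or 0.021 with the block), Slc1a3, a glutamate transporter, −0.21, and Gpr37, a receptor, −0.20. With the block 1 gene, Sox9, was higher and 2 were lower, Abca8a and Aqp4, the water channel of glial endfeet, which was at −0.81 (0.974, or 0.049 with the block) and was named after its values were seen. The Mueller call was lost without Control 2 (adjusted p = 0.187), and also without Z/Edn2 3 or Z/Edn2 4.

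Of the neuronal lists, that of retinal ganglion cells, the output neurons of the retina, fell furthest, by a mean of 0.38. Of its 12 measured genes 11 had negative log2 fold changes, 0 passed over all genes, 7 had an unadjusted p under 0.05 and 3 fell when adjusted over the list alone. These were Thy1, a surface glycoprotein, at −0.80 ± 0.189 (SE; limma adjusted p = 0.306), Nefm, a neurofilament protein, at −0.65 ± 0.121 (0.107), and Sncg, gamma-synuclein, at −0.46 ± 0.114 (0.347, or 0.0357 with the replicate block). Rbpms, an RNA-binding protein of these cells, was at −0.34 (0.817). The list's camera adjusted p was 1.22e-09, or 0.0223 with an estimated correlation, and the exact permutation p was 0.0286. With both the block and an estimated correlation, 0 of the 31 lists passed, and the smallest adjusted p was 0.175. Lists as unlike as hypoxia response (mean log2 change 0.69) and bipolar cells (−0.084) had this same value. Benjamini-Hochberg adjustment can give lists with different unadjusted p-values the same adjusted p, so the shared value does not mean equal evidence. The block leaves few residual degrees of freedom, so this setting cannot tell a lost call from low power.

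The lists of rods (mean log2 change −0.10) and amacrine cells (−0.079) also fell by camera, with adjusted p of 0.00624 and 0.0387. Both calls were lost with an estimated correlation (adjusted p = 0.686 and 0.214), and the exact permutation p was 0.686 and 0.0857, with 2 and 3 of the 4 same-numbered pairs lower. Of 20 rod and 13 amacrine genes 0 passed by limma either over all genes or over the list alone, and 0 rod and 2 amacrine genes had an unadjusted p under 0.05. Among rod genes, the log2 fold change was −0.19 for Reep6, −0.18 for Pde6g and −0.16 for Pde6b, the latter pair being subunits of the rod phosphodiesterase, and −0.11 for Nrl, the transcription factor of rod fate. Among amacrine genes it was −0.42 for Calb2, a calcium buffer, −0.30 for Slc32a1, the vesicular transporter of inhibitory transmitters, or −0.0099 as the mean of its probe sets, −0.27 for Gad1, which makes GABA, and 0.22 for Th, which makes dopamine precursors. The bipolar cell list had a mean log2 change of −0.084 and an adjusted p of 0.256, or 0.00355 with the replicate block and 0.175 with the block and an estimated correlation, and all 4 pairs were lower. By limma 0 of its 12 genes passed over all genes, over the list alone or at an unadjusted p under 0.05. Vsx1, a transcription factor of bipolar cells, had a log2 fold change of 0.34, Car8 −0.27, Isl1, another transcription factor, −0.15, and Trpm1, the transduction channel of ON bipolar cells, −0.14. As the mean of a gene's probe sets, Vsx1 was at 0.13, Car8 at −0.14 and Trpm1 at 0.034. Without Control 2 the adjusted p was 0.867 for rods, and without Control 1 it was 0.190 for amacrine cells. The rod call was also lost without Z/Edn2 3 or Z/Edn2 4, and the amacrine call without Control 2, Z/Edn2 2 or Z/Edn2 3.

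Retinal progenitor, immediate early and cholesterol synthesis genes rose as lists, by means of 0.18, 0.13 and 0.16, with camera adjusted p of 0.00675, 0.0222 and 0.00241. These calls were lost with an estimated correlation (adjusted p = 0.401, 0.202 and 0.274), and the exact permutation p, which takes no account of the pairs, was 0.229, 0.0571 and 0.114. In each of the 3 lists all 4 same-numbered pairs were higher in Z/Edn2. Of their 10, 13 and 11 measured genes, 0 passed by limma over all genes or over the list alone, and 2, 1 and 0 had an unadjusted p under 0.05. Progenitor examples were Sfrp2, a Wnt modulator, with a log2 fold change of 0.45, Fgf15 0.29, Atoh7, which ganglion cells need to form, 0.29, and Olig2 0.21. The immediate early genes Fos, Atf3, Junb and Egr2, transcription factors of acute responses, had log2 fold changes of 0.35, 0.31, 0.25 and 0.24. Insig1, which restrains sterol synthesis, was at 0.26, and the sterol enzymes Lss, Fdps and Hmgcs1 at 0.19, 0.19 and 0.17. The progenitor and immediate early calls were lost without Z/Edn2 1 (adjusted p = 0.327 and 0.478) and without Z/Edn2 4, the former also without Control 2 and the latter without Control 3.

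In all, 14 of 31 lists passed camera, 8 higher and 6 lower, 3 of which (hypoxia response, barrier endothelial and retinal ganglion cell) also passed with an estimated correlation, and 5 passed fry (those 3, reactive glia and astrocyte). With the replicate block and an estimated correlation, a setting of low power, 0 passed. In the authors' deposited table, 2029 of 45101 probe sets had an unadjusted p under 0.05, where chance gives 2255. Of these, 41 were at least 2-fold higher and 7 at least 2-fold lower, and Kcne3 had the smallest p (3.46e-07). With Benjamini-Hochberg adjustment 3 of the authors' p-values passed.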

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

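The comparisons with other splits of the arrays were planned, while the tests of the Edn2 probe set, of the endothelial lists and of the retinal ganglion cell list were chosen only after the results were seen.

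Edn2 did not pass in retinas that carried the Edn2 transgene, with a log2 fold change of 0.18 (limma adjusted p = 0.971, or 0.485 with the replicate block). Its Z/Edn2 value was nevertheless the higher within each same-numbered pair. A single mislabelled array is argued against by the hypoxia response list, whose lowest Z/Edn2 mean lay 0.576 above the highest Control mean, more than the larger SD of 0.0739. That list was picked after it was seen to separate the groups. It cannot show an exchange of all labels or whether the transgene was active. Compression near the bottom of the signal range stays open: the Control level of Edn2 lay above that of 12.1% of genes, but 3 genes with a lower level, Kcne3, Esm1 and Dlx1, were called higher, and levels of different probe sets cannot be compared. Whether the probe set reads the transgene's transcript stays open, and so does whether Edn2 RNA rose at all, which no other probe set measured.

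By camera the tip cell list was higher and the general endothelial list lower in Z/Edn2 retina, but only 2 of 15 and 2 of 20 genes passed, both calls were lost with an estimated correlation (adjusted p = 0.211 and 0.204), and the tip cell mean overlapped Control in Z/Edn2 2 (exact permutation p = 0.114). If only endothelial cells made the RNA of both lists, fewer such cells alone would lower both alike. Their difference shifted by 0.629, more than the larger SD of 0.124, with no overlap between the groups. The arrays read whole retina, so that premise was not tested and the shift does not exclude fewer endothelial cells. Within the general list itself, 15 of 20 log2 fold changes were negative and 5 positive. A different share of male pups is argued against as the whole cause, since the Y-linked mean was 7.24 ± 0.378 in Control and 7.14 ± 0.846 in Z/Edn2 (SD, n = 4 each) and, by the 95% bound, accounted for at most 49.3% of either list's mean change. A shift of endothelial cells towards the tip cell state with the genotype may account for the split, as a hypothesis found on the same data. Not all tip cell genes moved that way: 13 had positive log2 fold changes, while Kdr and Flt4 were at −0.23 each. Whether the tip cell genes rose in endothelial cells was not tested. A change in cell number together with a change in state stays open too.

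The retinal ganglion cell list was lower by camera (adjusted p = 0.0223 with an estimated correlation, or 0.175 with the block as well), though 0 of its 12 genes passed over all genes by limma and 7 had an unadjusted p under 0.05. RNA degradation is argued against as the whole cause, as far as the actin 3′ minus 5′ signal measures it: this was 1.03 ± 0.277 in Control and 1.05 ± 0.357 in Z/Edn2 (SD, n = 4 each) and, by the 95% bound, accounted for at most 24.6% of the mean change. For the Y-linked mean the bound was 35.5%. A loss of ganglion cells or lower marker RNA per cell may underlie the change, and neither was tested.

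For the counts of genes, chance is argued against, though not excluded, and only by splits that disregard the replicate numbers. Of 35 splits of the 8 arrays, 1, the real one, gave as many as 31 higher genes, and 1 gave as many as 9 lower genes. The highest count of any other split was 0 in either direction. A share of 1 in 35 is the smallest that these splits can give. The splits that part all 4 same-numbered pairs, as the real one does, number 8, too few for a share under 0.05; the real one called 40 genes and the highest other 0. Even against all splits, chance cannot be excluded for the count of 14 lists, since 2 of 35 splits gave as many and the highest other gave 15. That split set Control 4 with Z/Edn2 1, Z/Edn2 3 and Z/Edn2 4 against the rest. Among the splits that part all pairs, the highest other gave 9 lists.

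Of 230 groups of 4 arrays, 14 held an array far from the other 3 of its group, where chance gives about 11.5 at 5%, and 6 of them were in Z/Edn2 3. Among genes, Ndufa4l2 was at 10.59 in Z/Edn2 1 against 9.975 to 10.05 in the other Z/Edn2 arrays, and Ptprb was at 6.431 in Control 4 against 6.345 to 6.356. Tesc was at 6.939 in Z/Edn2 3 against 7.405 to 7.434. Slc32a1, in the same array, was at 7.852 against 8.437 to 8.527, and Hmgcs1 at 10.78 against 10.98 to 11.02. Steap4 was at 4.677 in Control 2 against 4.945 to 4.973. Reep6 was at 11.43 in Z/Edn2 2 against 11.1 to 11.13. Atoh7 was at 6.171 in Z/Edn2 4 against 6.38 to 6.401.

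The tip cell list had a mean of 6.464 in Z/Edn2 2 against 6.952 to 6.994, and the basement membrane list 7.25 in the same array against 7.831 to 7.917. The general endothelial list had a mean of 6.431 in Control 2 against 6.304 to 6.314. In Z/Edn2 3 the list of angiogenic and vascular guidance factors had a mean of 6.52 against 6.311 to 6.346, the array median was 6.275 against 6.141 to 6.157, and the bioD spike-in at the 5′ end was 9.295 against 11.32 to 11.61.

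Among probe sets without exactly 1 gene symbol, which the gene comparison did not use, 3 passed in a fit over all probe sets, each higher in Z/Edn2 (limma adjusted p = 0.0462). Their log2 fold changes were 0.937 for a probe set with several symbols, and 0.811 and 0.788 for a pair of probe sets without a symbol.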

How the results depend on the processing

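The covariate, the omission of 3 arrays, the omission of pairs and the block with an estimated correlation were chosen after seeing the data; the other alternatives were planned. Edn2 had a log2 fold change of 0.11 to 0.24 and adjusted p of 0.485 to 1 in all 20 alternatives that gave it a value. It has no other probe set and falls below the signal filter, so those alternatives gave no value. The 40 called genes kept their direction in every alternative that tested them, and 19 kept their calls without each of the 8 arrays in turn. Trend and robust options (31 higher, 9 lower), the mean of probe sets (31 and 9), quantile normalization again (32 and 9), median centring (27 and 10), the Y-linked covariate (31 and 9) and the omission of Control 1, Z/Edn2 1 and Z/Edn2 3 (25 and 10), every probe set counted (27 and 7) and a fold threshold of 1.5 (30 and 9) gave counts within 1.5 times the reported ones. Similar counts did not always mean the same genes. Of the 40 reported calls, 34 were kept with the mean of probe sets and 35 with median centring. The Y-linked covariate kept 35, and the omission of Control 1, Z/Edn2 1 and Z/Edn2 3 kept 24. Trend and robust options and quantile normalization again kept all 40. Of 514 values of the 25 called named genes under the alternatives, 401 passed. Over all alternatives adjusted p ranged from 0.000166 to 0.251 for Dlx1, 0.00106 to 0.251 for Igfbp2, 0.000813 to 0.231 for Egln3, 0.00121 to 0.230 for Esm1, 0.0162 to 0.262 for Tesc, 0.00562 to 0.606 for A2m, 0.00982 to 0.454 for Tpi1, 0.00403 to 0.139 for Slc39a8, 0.00365 to 0.311 for Ptprb and 0.0081 to 0.315 for AU021092. It ranged from 0.000524 to 0.196 for Aplnr, 0.00138 to 0.196 for Pdk1, 0.000268 to 0.157 for Slc38a5, 0.000681 to 0.125 for Mfsd2a, 0.00233 to 0.125 for Apln, 0.00291 to 0.125 for Pltp, 0.000206 to 0.0715 for Slco1c1, 8.38e-05 to 0.059 for Tek and 0.00147 to 0.0535 for Pfkfb3. Of the named genes, Kcne3, Adm, Ndufa4l2, Dlk1, Bnip3 and Muc2 kept their calls in every alternative that tested them. For lists it ranged from 0.000786 to 0.623 for Mueller glia, 2.76e-05 to 0.867 for rods, 0.00819 to 0.464 for amacrine cells, 1.94e-05 to 0.401 for progenitors, 0.00156 to 0.478 for immediate early genes and 1.33e-11 to 0.224 for barrier endothelium. It reached 0.4 for tip cells and for glycolysis, 0.464 for general endothelium, 0.274 for cholesterol synthesis, and 0.175 for hypoxia response, retinal ganglion cells, reactive glia and astrocytes. The count of higher genes was 49 with array weights and 71 with the replicate block, and the count of lower genes was 26 with the block and 2 without dim probe sets, where fewer genes were tested. With arrays or pairs left out it was 8 to 40 for higher and 1 to 10 for lower genes, with fewer arrays in each fit. The count of lists was 3 with an estimated correlation, 5 by fry and 0 with the block and an estimated correlation, and otherwise lay between 10 and 16; no list past the threshold changed direction in any alternative. Directions turned only for uncalled genes: Trpm1 was at 0.034 with the mean of probe sets, since its 3 other probe sets were above 0. Ece1 was at −0.11 without Control 2, −0.087 without Z/Edn2 1, −0.041 without Z/Edn2 4 and −0.027 with Control 1, Z/Edn2 1 and Z/Edn2 3 left out, and at most 0.295 otherwise with an array or pair left out. Ednrb was at −0.010 without replicate 1 and at most 0.21 with any other array or pair left out. Except where stated, the cause was not tested. Weak signal may limit Kcne3, Esm1, Dlx1 and Edn2, and the uncalled Gbp2 and Egr2, whose Control levels lay above those of at most 12.1% of genes, but the background of single probe sets was not measured.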

Other observations

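The test of neighbouring genes was chosen only after the calls were seen, while the gene lists were planned. Further genes rose in Z/Edn2 retina and are named here after their values were seen. Mt1, a metal-binding metallothionein, rose by 1.03 (limma adjusted p = 0.000614), and Plod2, which hydroxylates collagen lysines, by 0.91 (adjusted p = 0.00113). Myocd, a coactivator of smooth muscle genes, rose by 1.01 (adjusted p = 0.00478), and Anxa2, a calcium-dependent membrane protein, by 0.77 (adjusted p = 0.00768). Ccnd2, a cyclin of the G1 phase, rose by 1.11 (adjusted p = 0.0238) and Igf2, an imprinted growth factor, by 0.94 (adjusted p = 0.0465). Vegfa, the growth factor of endothelial cells, rose by 0.97 (adjusted p = 0.0148). It is a member of the hypoxia response list and was already counted among the members of that list that rose. The omission of a single array ended the call of Ccnd2 in 4 of 8 cases, of Igf2 in 6 and of Vegfa in 4, and the highest adjusted p was 0.121 for Ccnd2 without Z/Edn2 4, and 0.174 for Igf2 and 0.0747 for Vegfa without Control 3. Over all alternatives it reached 0.059 for Plod2, 0.111 for Myocd and 0.123 for Anxa2.

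Other cells of the vessel wall and eye showed no list past the threshold. The mean log2 change was 0.064 for mural cells (camera adjusted p = 0.286), 0.065 for basement membrane (0.464), 0.062 for the Norrin-Frizzled4 pathway (0.613) and 0.035 for angiogenic and vascular guidance factors (0.878). The list of angiogenic factors did not hold Vegfa, Adm, Apln or Angpt2, which were placed in the hypoxia and tip cell lists. Microglia and macrophages were at 0.0085 (0.557), erythroid cells at 0.063 (0.613), fibroblasts at 0.011 (0.873), retinal pigment epithelium at −0.027 (0.498) and lens at 0.13 (0.227). Cones were at 0.0049 (0.643), horizontal cells at −0.035 (0.701), and proliferation genes at 0.077 (0.41). Interferon response was at 0.058 (0.498), unfolded protein and amino acid stress at −0.0080 (0.643), and sex-linked genes at −0.29 (0.454). The sex-linked list mixed Xist (−0.83 ± 1.09, SE) with Y-linked genes, so its mean cannot show whether the pools were balanced in sex. In these lists 0 genes passed over all genes by limma, and an unadjusted p under 0.05 was reached by 4 microglia and macrophage, 3 mural and 2 fibroblast genes, by 1 gene each of the basement membrane, angiogenic, erythroid and lens lists, and by 0 of the others. With the replicate block 2 genes passed over all genes, both lower: Ctss, a lysosomal protease of the microglia list (adjusted p = 0.0445), and Postn, a matrix protein of the fibroblast list, at −0.49 (adjusted p = 0.0318). Adjusted over the list alone, Tagln of the mural list (0.32), Pgf of the angiogenic list (0.39) and Cd68 of the microglia list (0.59) were higher, and Ctss (−0.46) and P2ry12 (−0.59) of the microglia list lower. Camera's direction was down for cones and for microglia and macrophages, whose mean and median were above 0, and for fibroblasts, whose mean alone was above 0. It was also down for horizontal cells and for unfolded protein and amino acid stress, whose medians alone were above 0.

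A candidate explanation for some calls is a stretch of chromosome inherited with the transgene, which could place called genes near each other. Within 10 tested genes of another called gene lay 2 of the 40 called genes, Dlx1 and Pdk1, where random sets of genes gave a mean of 1.66. The share of 10000 random sets with as many was 0.575, so called genes were not crowded within that distance. A long stretch could hold linked calls further apart, and no site of the transgene was used. The explanation therefore stays open.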
